A study of Mus musculus with 8 samples.

How the data were processed

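Ribosome-bound RNA of kidney endothelium was profiled in 8 mice. Per the labels' protocols, endothelial cells carried a ribosomal protein L10a fused to EGFP under a tamoxifen-inducible Cdh5 Cre driver. Tagged ribosomes were affinity purified (translating ribosome affinity purification), and libraries were made with a targeted mouse transcriptome kit of Ion AmpliSeq on an Ion Chef and sequenced on an Ion Torrent S5. By these protocols animals were assigned at random within genotype and sex of each litter, but the sex of each is not given. The submitters' processing notes name the build mm10 and the Transcriptome Analysis Console with no role for either. The aligner, the counter and their settings are not given in the sources used here.

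The deposited table gives reads per 1000000 panel reads (RPM) for 23930 amplicons, 1 per gene, with 1 column per mouse. The authors divided the reads of each amplicon by the library's total on the panel and applied no other scaling between libraries, as the values show, since each column sums to 1000000. Within each library 100% of the values were whole multiples of the value of 1 read within 0.1 read. Read numbers were therefore recovered, giving 7093794 to 14877519 reads per library. A spreadsheet had turned 27 gene names into dates, and these names were restored. Amplicons hold PCR copies without molecular identifiers, so floors and sampling noise cover counting error only. Strand and amplicon positions are also not given, so genes that overlap or have near-identical relatives may share reads.

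Groups were taken from the genotype and treatment labels. Comparisons were LPS against saline in WT, the same in SOCS3iKEO, SOCS3iKEO against WT after LPS and after saline, the difference of the LPS effects (interaction), and LPS against saline over both genotypes with genotype as a covariate. The tests, samples, gene lists, naming rule and the first set of alternatives were fixed before the data were examined. The planned test was edgeR's quasi-likelihood test on counts, with limma on log2(value + 1) if the values were not counts. Because the unit is RPM, limma with a trended prior was the main test, on log2(scaled RPM + 1) after TMM scaling. FilterByExpr (minimum count 10, minimum total 15) kept 12820 genes. All 8 libraries entered 1 fit with a mean per group, so a group of 1 library takes its spread from the others. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. Adjusted p values are Benjamini-Hochberg, with a threshold of 0.05. On the recovered reads edgeR called 2065 genes for LPS in WT, 5194 for LPS in SOCS3iKEO, 6253 and 0 between genotypes after LPS and saline, 2114 for the interaction and 2617 for LPS over both genotypes. The TMM factors were 1.26 and 1.25 in WT saline, 1.25 in SOCS3iKEO saline, 0.994, 1.07 and 1.01 in WT LPS and 0.671 and 0.709 in SOCS3iKEO LPS.

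Camera tested 43 of 48 fixed lists (25 gene lists and 23 marker lists), those with 3 or more members tested, with a preset correlation of 0.01 on the same log2 values instead of the planned log2 CPM, and again with an estimated correlation. The gene lists covered NF-kB, STAT3 and acute-phase, AP-1, type I interferon, interferon-gamma, MHC class I and II, adhesion, chemokine, coagulation, junction, growth factor and Notch, transcription factor, DNA methylation, JAK-STAT, Toll-like receptor, cell cycle, glycolysis, oxidative phosphorylation, cholesterol, unfolded protein, cell death, oxidative stress, glycocalyx and ribosomal protein genes. The marker lists covered pan-endothelial, glomerular, arterial and lymphatic endothelium, tubule segments, podocyte, mural, fibroblast, immune, blood, urothelial, mitochondrial, housekeeping and sex-linked genes. Genes were named by rule: Socs3 first, then for LPS in WT the 10 called genes per direction with the largest log2 fold change, elsewhere 5 per direction, among genes with a mean of 3 or more on the log2 scale and every library of one arm on one side of the other (no such condition for the interaction). Where none passed, the 5 with the smallest p were named. Up to 4 members per list were named, called members with the largest change first. Some items under this rule are not reported here. Positions are gene bounds in mm10 from GENCODE M21. Transcript GC content and length were found for 12631 of 12820 genes (98.5%).

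Alternatives fixed beforehand were RLE size factors, no filter on low counts, DESeq2, limma on log2 CPM with prior count 2, pseudocounts 0.1 and 10, leaving out each library in turn, fits on the 5 WT or the 5 LPS libraries, other covariates for LPS over both genotypes, and an estimated correlation for lists. Alternatives chosen after seeing the data were edgeR on recovered reads, RPM as deposited without TMM, a GC and length correction, reads thinned to the smallest library, a term for Y-linked reads, the 5 libraries without Y-linked reads, the fit without SOCS3iKEO LPS libraries and lists on log2 CPM. The scripts were tested on simulated reads with 50 genes changed per fold size. For LPS in WT (12252 genes) 2%, 26%, 88% and 100% of genes changed 1.5, 2, 4 and 8 fold were called, with 9 false calls among 117. For LPS in SOCS3iKEO (12257 genes) 0%, 0%, 58% and 96% were called (6 false among 83). Between genotypes after LPS (12262 genes) 2%, 20%, 92% and 100% (4 false among 111) were called, and for LPS over both genotypes (12256 genes) 0%, 56%, 100% and 100% (7 false among 135). R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9 were used.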

Results

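Messenger RNA bound to tagged ribosomes of endothelial cells, the cells that line blood vessels, was measured in the kidneys of 8 mice with a targeted sequencing panel of 23930 amplicons, each standing for 1 gene. The mice received lipopolysaccharide (LPS, the endotoxin of gram-negative bacteria) at 250 µg in 250 µl, or saline, and kidneys were taken after 14 hours. There were 2 wild-type (WT) mice with saline, 3 WT mice with LPS, 2 mice labelled SOCS3iKEO with LPS and 1 mouse labelled SOCS3iKEO with saline, where SOCS3iKEO stands for an inducible endothelial knockout of Socs3. Each library came from 1 mouse. Library totals were 14262704 and 14877519 reads in WT saline, 11940405, 13507981 and 11002719 in WT LPS, 8431813 and 14096582 in SOCS3iKEO LPS and 7093794 in SOCS3iKEO saline. Between 14487 and 15715 amplicons had reads in a library, 1 read was worth 0.0672 to 0.141 reads per 1000000 panel reads (RPM), and 3 reads, used as a detection floor, corresponded to 0.202 to 0.423 RPM. Replicates of a group differed by far more than read sampling, with chi-square values of 23.7 to 80.7 per degree of freedom. Gene levels below are TMM-scaled RPM, as mean ± SD or the value of 1 library, except where given as deposited, and positions are those of the gene in mm10.

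The endothelial markers of the fixed list summed to 11631 and 12312 deposited RPM in WT saline, 11279 in SOCS3iKEO saline, 7061, 8370 and 8856 in WT LPS and 4778 and 6560 in SOCS3iKEO LPS. Metallothionein Mt1 alone took 5.73% and 4.16% of the reads of the SOCS3iKEO LPS libraries, whose 10 most abundant genes took 15% and 12.7%, against 4.87% to 5.07% in the saline libraries and 6.21% to 7.05% in WT LPS. The SOCS3iKEO LPS libraries stood apart on the first principal component, which held 67.8% of the variance. Along the second, with 19.8%, the WT LPS libraries lay away from all saline libraries. Reads on 4 Y-linked genes were 3805 in WT saline 2, 3987 in WT LPS 2 and 3320 in WT LPS 3, and 1 to 3 in each of the other 5 libraries, which include every SOCS3iKEO library. The animal numbers in the labels formed 2 runs, 1 with the WT saline and SOCS3iKEO LPS mice and the other with the WT LPS and SOCS3iKEO saline mice. A shift between runs would therefore coincide with LPS within each genotype, with genotype within each treatment and with the interaction.

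**Figure D1:**
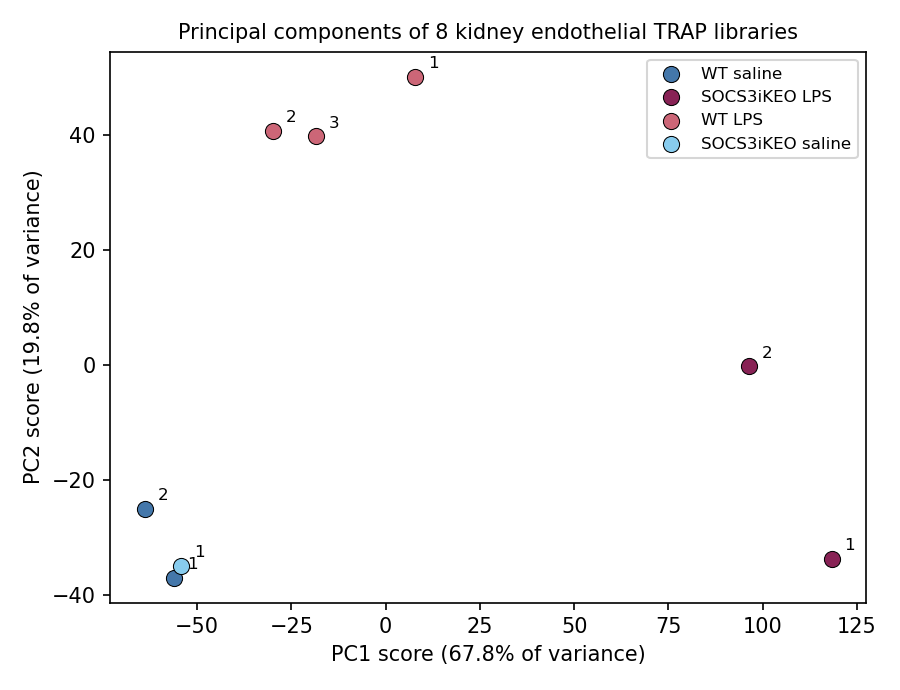
Scores of the 8 libraries on the first and second principal components of log2(scaled RPM + 1), 1 point per library, coloured by group. The SOCS3iKEO LPS libraries lie at 118 and 96.4 on the first component, against -63.9 to -54.2 for the saline libraries and -29.9 to 7.83 for WT LPS.

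Socs3, the feedback inhibitor of JAK-STAT signalling that the genotype targets (chromosome 11, 117966079 to 117970047, minus strand), was near the detection floor after saline, at 0.631 and 0.202 RPM in WT and 0.282 RPM in SOCS3iKEO as deposited. After LPS it stood at 9.88, 1.26 and 2.36 RPM in WT and at 2.37 and 1.77 RPM in SOCS3iKEO as deposited, from 118, 17, 26, 20 and 25 reads, or at 9.94, 1.18 and 2.34 against 3.53 and 2.50 scaled RPM. Over both genotypes Socs3 rose with LPS (log2 fold change 1.70, SE 0.46, adjusted p = 0.028, limma). The call was lost without WT saline 1 (adjusted p = 0.0541), WT saline 2 (0.0847) or SOCS3iKEO LPS 2 (0.0578). A pseudocount of 10 (0.103) or no filter on low counts (0.0541) lost it. Within WT its log2 fold change was 1.71 (SE 0.57, adjusted p = 0.0711), and within SOCS3iKEO 1.70 (SE 0.76, adjusted p = 0.0972). In WT it passed with DESeq2 (log2 fold change 3.77, adjusted p = 0.000444), edgeR (3.72, 0.0318), limma on log2 CPM (2.81, 0.0416), a pseudocount of 0.1 (2.99, 0.0405), a sex term (1.92, 0.0132) and without WT LPS 2 (2.19). In SOCS3iKEO it passed with DESeq2 (3.81, 0.0272), log2 CPM (3.01, 0.0417), a pseudocount of 0.1 (3.24, 0.0388), a sex term (1.70, 0.0281) and without WT LPS 1 (1.70), and not with edgeR (3.66, 0.0988). Between genotypes after LPS it did not pass (log2 fold change -0.11, SE 0.57, adjusted p = 0.885). The position of its amplicon relative to the deleted part was not given, so Socs3 does not check the genotype labels, and the libraries are called by those labels throughout. Rpl10a, the tagged ribosomal protein, was not analysed here.

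The first comparison asked what LPS changed in WT. Tubule markers were also present, so a change need not be endothelial. Lcn2, which encodes the siderophore-binding protein lipocalin 2 (chromosome 2, 32384633 to 32388252), rose most, from 1.4 ± 0.379 scaled RPM (n = 2) to 3283 ± 364 (n = 3; log2 fold change 10.42, SE 0.20, adjusted p = 1.2e-08). Ccl2, a chemokine that attracts monocytes (chromosome 11, 82035571 to 82037453), rose from 1.72 ± 0.232 to 211 ± 37.5 (log2 fold change 6.27, SE 0.29, adjusted p = 1.27e-05). Also among the 10 that rose most were Mctp2 at 7.19, Serpina3f at 6.62, Zbtb16 at 6.18, Fga at 6.18, Fgg at 6.04, Ifi205 at 5.94 and Serpina3g at 5.50 on the log2 scale. Fga and Fgg encode chains of fibrinogen. Csf3, the gene of granulocyte colony-stimulating factor, was listed at 0 in both WT saline libraries and reached 57 ± 34.6 in WT LPS, at least 348-fold higher against a floor of 3 reads per library. Npr3, the clearance receptor of natriuretic peptides (chromosome 15, 11839896 to 11907287), fell most, from 143 ± 56.2 to 2.29 ± 1.04 (log2 fold change -5.45, SE 0.35, adjusted p = 5.03e-05), and Igfbp5, a binding protein of insulin-like growth factors, fell from 1319 ± 147 to 37 ± 13.9 (log2 fold change -5.19, SE 0.43). The other genes that fell most were Btnl9 at -4.55, Chrm3 at -4.13, Nccrp1 at -4.10, Cryab at -3.98, Ephx1 at -3.77, Samd12 at -3.72, Wfdc15b at -3.55 and Nrep at -3.44, of which Chrm3 encodes a muscarinic acetylcholine receptor and Cryab a small heat shock protein. For each of these 20 genes all 3 WT LPS libraries lay on one side of both WT saline libraries, as the naming rule required. Serpina3f, Serpina3g and Ifi205 have near-identical relatives that may share reads.

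Inflammatory gene groups rose in WT. Of 15 tested NF-kB feedback and target genes, 8 rose and 0 fell (9 and 0 when adjusted over the list alone), including Nfkbiz (4.09) and Ikbke (2.41). For NF-kB genes camera gave adjusted p = 8.73e-08, and adjusted p = 0.132 with an estimated correlation. Their median log2 fold change was 0.96. STAT3 and acute-phase genes rose in 16 of 18 cases (16 and 1 when adjusted over the list alone), with a median of 2.56, led by Lcn2, Fga, Fgg and Fgb (4.81). For STAT3 and acute-phase genes camera gave adjusted p = 9.02e-15, and adjusted p = 0.251 with an estimated correlation. Among 22 type I interferon-stimulated genes 6 rose and 2 fell (10 and 3 when adjusted over the list alone), with Zbp1 (2.52) and Mx1 (2.40) among those that rose. For interferon-stimulated genes camera gave adjusted p = 0.000321, and adjusted p = 0.43 with an estimated correlation. Interferon-gamma GTPases and chemokines rose in 7 of 14 (10 and 0 when adjusted over the list alone), such as the chemokines Cxcl9 (4.88) and Cxcl10 (2.90). For the interferon-gamma list camera gave adjusted p = 5.33e-06, and adjusted p = 0.347 with an estimated correlation. MHC class I presentation genes rose in 8 of 14 (9 and 0 when adjusted over the list alone), among them Tap1 (1.82) and H2-Q6 (1.47). For MHC class I genes camera gave adjusted p = 1.04e-05, and adjusted p = 0.34 with an estimated correlation. H2-Q6 has near-identical relatives. For MHC class II presentation 1 of 7 rose, Cd74 (1.92) (1 and 0 when adjusted over the list alone). For MHC class II genes camera gave adjusted p = 0.011, and adjusted p = 0.498 with an estimated correlation. Chemokines and cytokines rose in 9 of 18 and 1 fell (10 and 2 when adjusted over the list alone), with Cxcl1 (4.28) and Ccl5 (4.17) beside Ccl2 and Csf3. For chemokines and cytokines camera gave adjusted p = 1.04e-05, and adjusted p = 0.132 with an estimated correlation. Their median was 1.38, or 1.44 with 2 members that were at 0 in one group set to 3 reads. Leukocyte adhesion molecules rose in 5 of 13 (5 and 1 when adjusted over the list alone), namely Selp (4.27), Sele (3.36), Vcam1 (2.10) and Icam1 (1.97) and 1 more. For adhesion molecules camera gave adjusted p = 0.0105, and adjusted p = 0.251 with an estimated correlation. Selp and Sele encode P- and E-selectin. The numbers that rose and fell on RPM as deposited were 4 and 3 for interferon-stimulated genes, 6 and 0 for MHC class I genes, 10 and 2 for chemokines and cytokines and 5 and 2 for adhesion molecules, and counts of the other lists named here differed by at most 1 member.

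LPS receptor and Toll-like receptor signalling genes rose in 6 of 14 (6 and 0 when adjusted over the list alone), including Irak3, an inhibitor of this pathway, at 2.83 and the co-receptor Cd14 at 2.71. For Toll-like receptor genes camera gave adjusted p = 0.000132, and adjusted p = 0.151 with an estimated correlation. Of 22 JAK-STAT components and regulators 4 rose and 0 fell (4 and 0 when adjusted over the list alone), including Osmr (2.28), Socs2 (1.46) and Stat3 (1.23). For JAK-STAT genes camera gave adjusted p = 0.0264, and adjusted p = 0.296 with an estimated correlation. The JAK-STAT median was 0.25 but -0.04 on RPM as deposited. AP-1 and immediate early genes rose in 3 of 16 (3 and 0 when adjusted over the list alone), which were Fosl1 (4.85), Maff (1.64) and Junb (1.22). That list had a median of -0.04, a mean of 0.30 and no camera call (Up, adjusted p = 0.384). Coagulation and fibrinolysis genes rose in 7 of 17 and 2 fell (9 and 3 when adjusted over the list alone). For coagulation genes camera gave adjusted p = 0.016, and adjusted p = 0.347 with an estimated correlation. Among them were the plasminogen activator Plat at 2.76 and factor VIII, F8, at -2.58. Genes of vascular growth factor, Tie, Notch and ALK1 signalling fell in 7 of 20 and 0 rose (1 and 7 when adjusted over the list alone). The apelin receptor Aplnr went from 44 ± 6.36 to 3.66 ± 1.88 scaled RPM (log2 fold change -3.34, SE 0.35), and other members were Hey1 (-2.80), Nrp1 (-1.99) and Esm1 (-1.98). The list median was -0.09 (camera adjusted p = 0.128). Endothelial transcription factors fell in 6 of 16, such as Mef2c (-1.87), and 2 rose, such as Nr2f2 (1.89) (2 and 6 when adjusted over the list alone; camera adjusted p = 0.283). Endothelial junction and permeability genes rose in 2 of 14, Jam2 (1.95) and Rasip1 (1.17), and 1 fell, Plvap (-0.87) (2 and 2 when adjusted over the list alone). That list had a median of -0.13, a mean of 0.05 and camera Up at adjusted p = 0.782. DNA methylation and demethylation genes rose in 2 of 16, Tdg (1.14) and Mbd1 (1.14), and the demethylase Tet1 fell (-2.07; 2 and 1 when adjusted over the list alone). Their median was 0.03, and -0.24 on RPM as deposited (camera adjusted p = 0.295). Members called higher and lower on RPM as deposited were 4 and 0 for Toll-like receptor genes, 6 and 3 for coagulation genes and 2 and 8 for transcription factors, and counts of the other lists named here differed by at most 1 member.

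Among metabolic and stress groups, ribosomal protein genes rose in 7 of 8 tested (7 and 0 when adjusted over the list alone), including Rpl32 (1.74) and Rpl4 (1.56). For ribosomal protein genes camera gave adjusted p = 6.94e-05, and adjusted p = 0.345 with an estimated correlation. Cholesterol synthesis and uptake genes rose in 5 of 16 (9 and 0 when adjusted over the list alone), among them Fdft1 at 1.59. For cholesterol genes camera gave adjusted p = 0.000639, and adjusted p = 0.345 with an estimated correlation. Unfolded protein response genes rose in 4 of 15 (7 and 1 when adjusted over the list alone), with Xbp1 (1.45) and Atf4 (1.26). For unfolded protein genes camera gave adjusted p = 0.000321, and adjusted p = 0.151 with an estimated correlation. Cell death and inflammasome genes rose in 5 of 18 (9 and 2 when adjusted over the list alone), among them the inflammatory caspase Casp4 at 2.87 and the necroptosis effector Mlkl at 1.77. For cell death genes camera gave adjusted p = 0.00145, and adjusted p = 0.345 with an estimated correlation. Oxidative stress and metallothionein genes rose in 5 of 12 and 1 fell (6 and 1 when adjusted over the list alone). For oxidative stress genes camera gave adjusted p = 0.00413, and adjusted p = 0.409 with an estimated correlation. They were led by Mt1, from 117 ± 36 to 4591 ± 3649 scaled RPM (log2 fold change 4.97) and Sod2, mitochondrial superoxide dismutase, at 2.53. Glycocalyx and matrix remodelling genes rose in 6 of 17 and 1 fell (7 and 2 when adjusted over the list alone), with the proteases Adamts4 (3.42) and Adamts9 (2.03) and collagen Col4a1 (1.83). For glycocalyx genes camera gave adjusted p = 0.00506, and adjusted p = 0.309 with an estimated correlation. Glycolysis genes rose in 2 of 12, Pfkfb3 (1.80) and Hk2 (1.75) (3 and 0 when adjusted over the list alone). For glycolysis genes camera gave adjusted p = 0.0101, and adjusted p = 0.34 with an estimated correlation. Cell cycle genes rose in 2 of 16, Tyms (0.95) and Rrm2 (0.93) (2 and 0 when adjusted over the list alone; camera adjusted p = 0.288). Of 21 oxidative phosphorylation genes 0 passed (0 and 0 when adjusted over the list alone; camera adjusted p = 0.174). The cell cycle and oxidative phosphorylation medians went from 0.16 to -0.12 and from 0.18 to -0.11 on RPM as deposited. The numbers that rose and fell on that scale were 2 and 1 for cholesterol genes, 5 and 3 for cell death genes, 5 and 2 for glycocalyx genes and 0 and 1 for cell cycle genes, and counts of the other lists named here differed by at most 1 member.

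Markers of cell types also moved. Endothelial markers summed to 7061 to 8856 deposited RPM in WT LPS and 11631 and 12312 in WT saline. Arterial endothelial markers fell in 5 of 9 (0 and 8 when adjusted over the list alone), with Ltbp4 (-2.03) and Efnb2 (-1.63) beside Hey1. For arterial markers camera gave adjusted p = 0.000321, and adjusted p = 0.151 with an estimated correlation. Pan-endothelial markers rose in 1 of 16, Ramp2 (1.05), and fell in 3, Cd34 (-1.07) and Tie1 (-0.98) and Plvap (1 and 4 when adjusted over the list alone; camera adjusted p = 0.281). Of 5 glomerular endothelial markers 1 rose, Plat, and 2 fell, with Gata5 (-1.74) (2 and 3 when adjusted over the list alone; camera adjusted p = 0.689). Of 4 lymphatic markers 1 rose, Lyve1 (1.64) (2 and 0 when adjusted over the list alone; camera adjusted p = 0.283). Proximal tubule markers fell in 4 of 14 (0 and 8 when adjusted over the list alone), with Gatm (-3.31) and Slc5a12 (-1.93). For proximal tubule markers camera gave adjusted p = 0.0002, and adjusted p = 0.347 with an estimated correlation. They summed to 1255 to 2054 deposited RPM in WT LPS, against 2593 to 2758 in saline libraries. Loop of Henle markers fell in 4 of 6 (0 and 5 when adjusted over the list alone), with Slc12a1 (-2.23) and Kcnj1 (-2.16). For loop of Henle markers camera gave adjusted p = 0.00506, and adjusted p = 0.34 with an estimated correlation. Principal cell markers of the collecting duct fell in 3 of 6 (0 and 4 when adjusted over the list alone), with Aqp3 (-1.48) and Aqp2 (-1.41). For principal cell markers camera gave adjusted p = 0.00633, and adjusted p = 0.34 with an estimated correlation. Distal convoluted tubule markers fell in 1 of 4, Calb1 (-2.19) (0 and 1 when adjusted over the list alone; camera adjusted p = 0.281). Intercalated cell markers fell in 1 of 6, Slc4a1 (-1.81) (0 and 1 when adjusted over the list alone; camera adjusted p = 0.288). Injured tubule markers rose in 3 of 7, Havcr1 (3.70), Spp1 (3.31) and Sox9 (2.57) (3 and 0 when adjusted over the list alone). For injured tubule markers camera gave adjusted p = 0.00227, and adjusted p = 0.34 with an estimated correlation. Their median was 2.02, or 2.57 with 1 member at 0 after saline set to 3 reads. Neutrophil markers rose in 2 of 6, S100a9 (1.71) and S100a8 (1.47) (2 and 0 when adjusted over the list alone). For neutrophil markers camera gave adjusted p = 0.0216, and adjusted p = 0.408 with an estimated correlation. They summed to deposited RPM of 1.26 and 1.48 in WT saline and 9.46, 5.77 and 11.2 in WT LPS. Podocyte markers rose in 2 of 6, with Cdkn1c (2.09) (2 and 1 when adjusted over the list alone; camera adjusted p = 0.283). Their median of 0.11 was -0.05 on RPM as deposited. That scale gave 0 and 8 for arterial markers, 0 and 5 for pan-endothelial markers and 0 and 8 for proximal tubule markers, and counts of the other lists named here differed by at most 1 member.

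In the remaining marker lists few passed. Mural and mesangial markers fell in 1 of 7, Gata3 (-1.02) (0 and 1 when adjusted over the list alone; camera adjusted p = 0.36). Fibroblast markers rose in 1 of 5, Dcn (1.26) (1 and 0 when adjusted over the list alone; camera adjusted p = 0.983). Of 7 macrophage markers 0 passed (0 and 0 when adjusted over the list alone; camera adjusted p = 0.174). Platelet markers rose in 1 of 3, Pf4 (2.29) (1 and 0 when adjusted over the list alone). Platelet markers had a median of -0.19, a mean of 0.54 and camera Up at adjusted p = 0.578. The single tested T and NK cell marker, Lck, rose (1.14). Of the others, 0 of 1 erythroid and 0 of 2 urothelial markers passed. No B cell or mitochondrially encoded gene was tested. Housekeeping genes fell in 1 of 6, Gusb (-1.23) (0 and 1 when adjusted over the list alone; camera adjusted p = 0.583). Of 4 sex-linked genes 0 passed (0 and 0 when adjusted over the list alone; camera adjusted p = 0.566). Higher and lower calls on RPM as deposited were 0 and 1 for fibroblast markers, and counts of the other lists named here differed by at most 1 member.

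In all, limma on log2(scaled RPM + 1) called 2005 of 12820 genes in WT at an adjusted p under 0.05, 878 higher and 1127 lower after LPS, with 609 and 873 past a 2-fold change. Camera called 24 of 43 lists, 20 up and 4 down, and 0 with an estimated correlation. On RPM as deposited the median of all genes was -0.26 instead of -0.02 and the share of higher calls 19.9% instead of 43.8% (586 higher, 2366 lower), so directions are relative to that shift. The count of genes was 348 without WT saline 1, 564 without WT saline 2, 1093 without WT LPS 3 and 1078 with no filter on low counts. Of 103 calls among genes open to naming 47, 39, 11, 8 and 22 were lost without WT saline 1 and 2 and WT LPS 1, 2 and 3. They included Adamts9, Aqp2, Aqp3, Atf4, Calb1, Cd14, Cd34, Cd74, Cdkn1c, Cxcl10, Dcn, Efnb2, Fdft1, Fgb, Gata3, Gata5, Gusb, Havcr1, Hk2, Junb, Kcnj1, Lck, Lyve1, Maff, Mbd1, Mlkl, Nrp1, Pf4, Pfkfb3, Plat, Plvap, Ramp2, Rasip1, Rpl32, Rpl4, Rrm2, S100a8, S100a9, Slc12a1, Slc4a1, Socs2, Spp1, Stat3, Tap1, Tdg, Tie1, Tyms, Vcam1 and Xbp1, with adjusted p between 0.0501 (Lyve1 without WT LPS 1) and 0.337 (Aqp2 without WT saline 1) where the call was lost. With no filter on low counts 41 were lost, at adjusted p of 0.0504 or more, and with a pseudocount of 10 those of Fgb, Socs2, Hk2, Dcn, S100a8 and S100a9, at 0.0695 to 0.31. On RPM as deposited the calls of Tyms, Rrm2, Ramp2 and Dcn were among those lost, at 0.0553 to 0.0972. Gata5 and Lck lost their calls with edgeR (log2 fold changes -2.33 and 1.81, adjusted p = 0.0544 and 0.073) and limma on log2 CPM (-2.52 and 1.72, 0.0796 and 0.0876). Tie1 lost its call with the GC and length correction at a log2 fold change of -0.95 (0.0533).

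**Figure D2:**
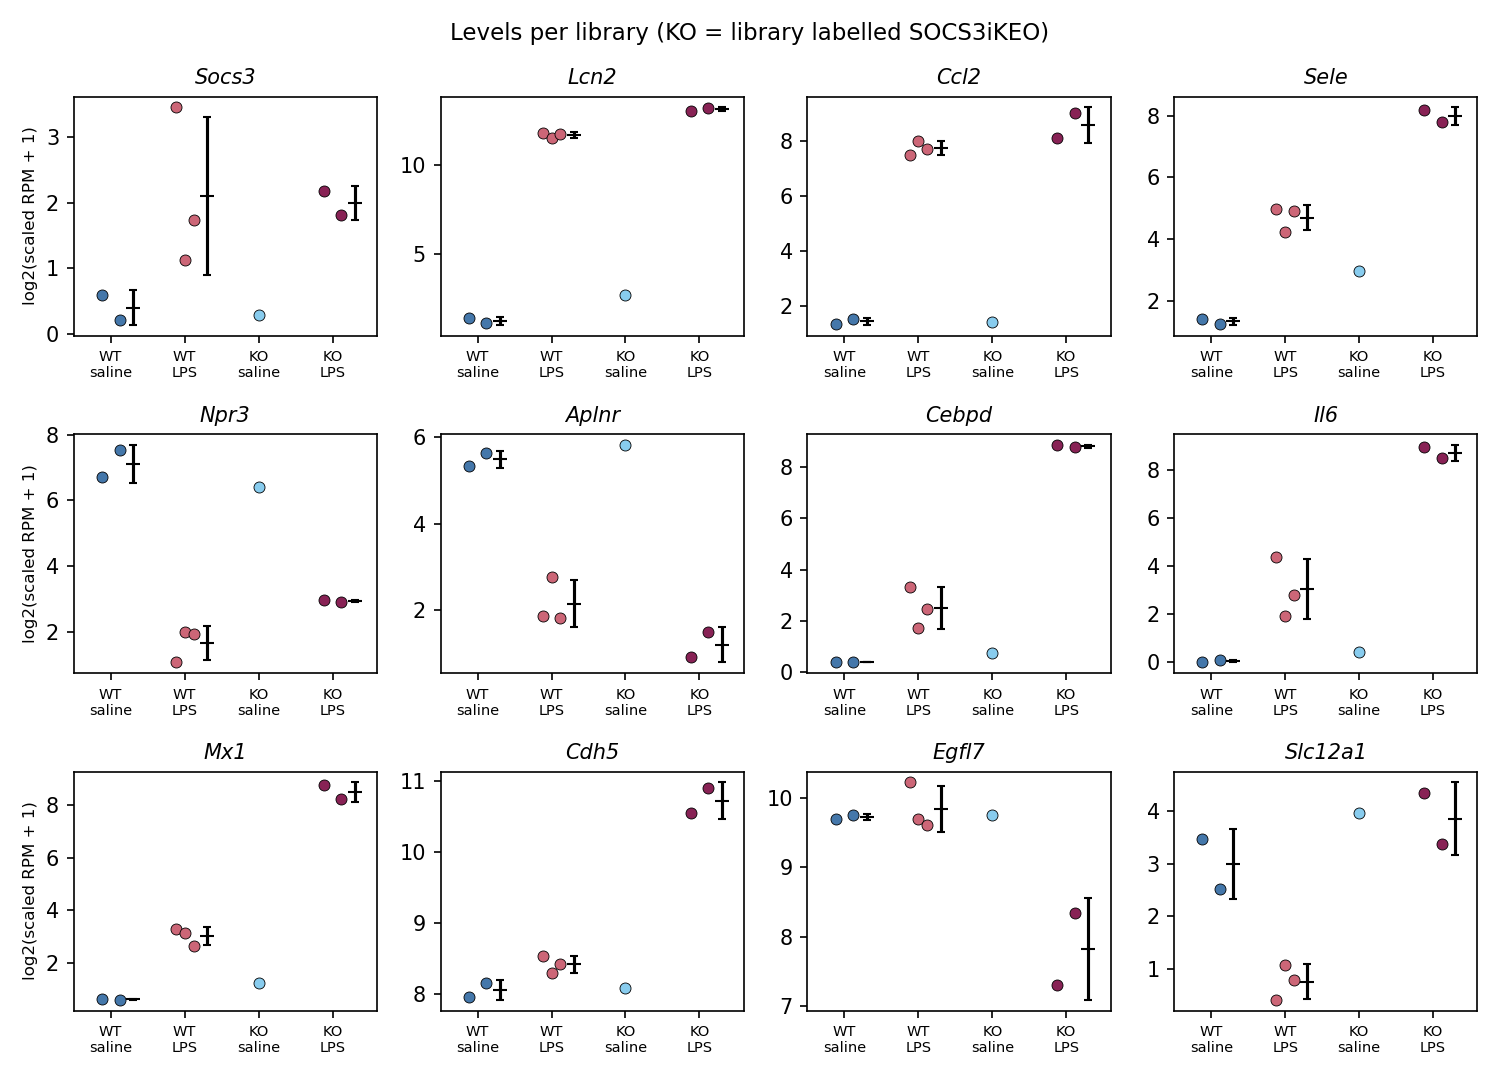
Levels of 12 genes as log2(scaled RPM + 1) in each library, with bars for the group mean ± SD (no SD for the single SOCS3iKEO saline library). Lcn2 was at 1.4 ± 0.379 scaled RPM in WT saline, 3283 ± 364 in WT LPS and 8938 ± 649 in SOCS3iKEO LPS, and Cebpd at 0.328 ± 0.00769, 5.33 ± 3.46 and 443 ± 15.8.

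In the libraries labelled SOCS3iKEO, LPS was compared with 1 saline library, whose spread was taken from the other groups. Lcn2 rose from 5.54 to 8938 ± 649 scaled RPM (log2 fold change 10.41, SE 0.27, adjusted p = 1.8e-07), and the neutrophil chemokine Cxcl2 from 0.339 to 876 ± 138 (log2 fold change 9.35, SE 0.35). Mt1 rose from 124 to 72002 ± 18782 (log2 fold change 9.15, SE 0.81) and Akap12, a scaffold of protein kinase A, from 1.13 to 1142 ± 612 (log2 fold change 8.96, SE 1.03). Csf3 was listed at 0 after saline and reached 563 ± 20.1, at least 1659-fold higher against 3 reads. The genes that fell most were Hs1bp3 at -5.63, 2700081O15Rik at -5.29, Btnl9 at -5.01, Exoc3l2 at -4.97 and Kank4 at -4.90 on the log2 scale. All 18 of 18 STAT3 and acute-phase genes rose (18 and 0 when adjusted over the list alone), with a median of 4.35. For STAT3 and acute-phase genes camera gave adjusted p = 1.45e-11, and adjusted p = 0.329 with an estimated correlation. AP-1 and immediate early genes rose in 14 of 16 (15 and 0 when adjusted over the list alone), with a median of 2.57, or 2.81 with 1 member at 0 set to 3 reads. For AP-1 genes camera gave adjusted p = 1.04e-06, and adjusted p = 0.337 with an estimated correlation. Type I interferon-stimulated genes rose in 16 of 22 (17 and 0 when adjusted over the list alone). For interferon-stimulated genes camera gave adjusted p = 9.48e-08, and adjusted p = 0.337 with an estimated correlation. Chemokines and cytokines rose in 12 of 18 (12 and 0 when adjusted over the list alone). For chemokines and cytokines camera gave adjusted p = 1.12e-05, and adjusted p = 0.231 with an estimated correlation. MHC class I presentation genes rose in 12 of 14 (12 and 0 when adjusted over the list alone). For MHC class I genes camera gave adjusted p = 5.06e-05, and adjusted p = 0.337 with an estimated correlation. Among markers of other cells, proximal tubule genes rose in 6 of 14 (6 and 0 when adjusted over the list alone). For proximal tubule markers camera gave adjusted p = 0.0129, and adjusted p = 0.497 with an estimated correlation. Injured tubule genes rose in 6 of 7 (7 and 0 when adjusted over the list alone). For injured tubule markers camera gave adjusted p = 0.00189, and adjusted p = 0.337 with an estimated correlation. Neutrophil genes rose in 5 of 6 (6 and 0 when adjusted over the list alone). For neutrophil markers camera gave adjusted p = 0.00443, and adjusted p = 0.337 with an estimated correlation. The numbers that rose and fell in SOCS3iKEO on RPM as deposited were 16 and 0 for STAT3 and acute-phase genes, 12 and 0 for AP-1 genes, 14 and 0 for interferon-stimulated genes, 9 and 1 for chemokines and cytokines, 7 and 1 for MHC class I genes and 1 and 0 for proximal tubule markers, and counts of the other lists named here differed by at most 1 member.

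In SOCS3iKEO limma called 5649 genes, 2589 higher and 3060 lower after LPS. On RPM as deposited it called 1219 higher and 5687 lower, with the share of higher calls at 17.7% instead of 45.8% and the median of all genes at -0.73 instead of -0.08. The LPS responses of the genotypes, which share no library, had 604 genes called higher in both and 630 called lower in both, against 177 and 269 for independent lists. A further 15 and 36 were called in opposite directions. Of the 2005 genes called in WT 1738 (86.7%) had the same sign in SOCS3iKEO. Across all genes, which are not independent replicates, the log2 fold changes correlated at r = 0.567 and rho = 0.489.

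The next comparison asked what differed between SOCS3iKEO and WT after LPS (n = 2 and 3). Cebpd, a transcription factor of the acute-phase response (chromosome 16, 15887286 to 15891031), was at 443 ± 15.8 scaled RPM in SOCS3iKEO and 5.33 ± 3.46 in WT (log2 fold change 6.28, SE 0.41, adjusted p = 3.83e-05). Il6, the cytokine interleukin 6 (chromosome 5, 30013114 to 30019981), was at 425 ± 96.1 against 9.51 ± 9.05 (log2 fold change 5.69, SE 0.58, adjusted p = 0.000156). The interferon-induced chemokine Cxcl10 (chromosome 5, 92346638 to 92348889) was at 19332 ± 15490.2 against 255 ± 158 (log2 fold change 6.13, SE 0.57, adjusted p = 0.000113). Cxcl11, another ligand of the receptor CXCR3, and Mx1, an interferon-induced antiviral GTPase, were higher by 5.46 and 5.46 on the log2 scale. Cyp26b1, an enzyme that degrades retinoic acid, fell furthest relative to WT, at 5.34 ± 0.193 against 428 ± 206 (log2 fold change -5.93, SE 0.53, adjusted p = 0.000101), followed by Slc9a3r2 at -5.19, Pkn3 at -5.16, Arhgap27 at -5.05 and Exoc3l2 at -4.92. For each of these 10 genes both SOCS3iKEO libraries lay on one side of all 3 WT libraries, as the naming rule required.

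AP-1 and immediate early genes were higher in SOCS3iKEO in 15 of 16 (16 and 0 when adjusted over the list alone), with Fos (4.23), Fosl2 (4.04) and Egr1 (3.57) and a median of 2.27. For AP-1 genes camera gave adjusted p = 3.92e-06, and adjusted p = 0.423 with an estimated correlation. STAT3 and acute-phase genes were higher in 13 of 18 (13 and 0 when adjusted over the list alone), with Timp1 (3.36), Steap4 (3.13) and Pim1 (2.58) beside Cebpd. For STAT3 and acute-phase genes camera gave adjusted p = 3.92e-06, and adjusted p = 0.423 with an estimated correlation. Type I interferon-stimulated genes were higher in 16 of 22 and lower in 1 (16 and 1 when adjusted over the list alone), with Mx2 (4.10) and Rsad2 (3.45). For interferon-stimulated genes camera gave adjusted p = 6.5e-05, and adjusted p = 0.423 with an estimated correlation. Interferon-gamma GTPases and chemokines were higher in 8 of 14 and lower in 1 (8 and 1 when adjusted over the list alone), with Cxcl9 (3.97). For the interferon-gamma list camera gave adjusted p = 0.0163, and adjusted p = 0.626 with an estimated correlation. NF-kB genes were higher in 8 of 15 and lower in 1 (8 and 1 when adjusted over the list alone), with Rel (3.48) and Nfkbiz (2.17). For NF-kB genes camera gave adjusted p = 0.0248, and adjusted p = 0.423 with an estimated correlation. Chemokines and cytokines were higher in 9 of 18 (11 and 0 when adjusted over the list alone), with Cxcl2 (4.95), Cxcl1 (3.70) and Csf3 (3.46). For chemokines and cytokines camera gave adjusted p = 0.000409, and adjusted p = 0.423 with an estimated correlation. Adhesion molecules were higher in 7 of 13 and lower in 2 (7 and 2 when adjusted over the list alone). For adhesion molecules camera gave adjusted p = 0.0462, and adjusted p = 0.423 with an estimated correlation. Selp was at 838 ± 262 against 39 ± 22.3 scaled RPM and Sele at 255 ± 49.2 against 25.7 ± 6.95 (log2 fold changes 4.51 and 3.29). MHC class I presentation genes were higher in 10 of 14 and lower in 1 (10 and 1 when adjusted over the list alone), with H2-Q4 (1.98) and Tapbp (1.60). For MHC class I genes camera gave adjusted p = 0.00572, and adjusted p = 0.423 with an estimated correlation. Of 7 class II genes 0 passed (0 and 0 when adjusted over the list alone; camera adjusted p = 0.556). JAK-STAT components were higher in 13 of 22 and lower in 4 (13 and 4 when adjusted over the list alone), with Socs2 (3.03), Jak2 (2.30) and Osmr (2.23) higher and Tyk2 (-3.98) lower. For JAK-STAT genes camera gave adjusted p = 0.0296, and adjusted p = 0.423 with an estimated correlation. Toll-like receptor signalling genes were higher in 7 of 14 and lower in 3 (7 and 3 when adjusted over the list alone; camera adjusted p = 0.184), with Cd14 (4.75) and Tlr3 (2.36). Their median went from 0.55 to -0.01 on RPM as deposited. In this comparison RPM as deposited gave higher and lower calls of 13 and 0 for AP-1 genes, 10 and 2 for interferon-stimulated genes, 6 and 3 for the interferon-gamma list, 5 and 4 for NF-kB genes, 7 and 0 for chemokines and cytokines, 5 and 4 for adhesion molecules, 3 and 1 for MHC class I genes, 0 and 2 for MHC class II genes, 8 and 7 for JAK-STAT genes and 5 and 4 for Toll-like receptor genes, and counts of the other lists named here differed by at most 1 member.

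With 50.7% of all genes called between genotypes, endothelial ones moved both ways. Their markers summed to 4778 and 6560 deposited RPM in SOCS3iKEO LPS and 7061 to 8856 in WT LPS. Endothelial transcription factors were higher in 8 of 16, such as Ets2 (2.41), and lower in 6 (8 and 6 when adjusted over the list alone). Among those lower were Lyl1 (chromosome 8, 84701457 to 84704715), at 0.1 ± 0.142 against 23.6 ± 5.06 scaled RPM (log2 fold change -4.47) and Sox18 (-4.30) and Elk3 (-2.75). Their median was 0.59, their mean -0.10 and camera gave Up at adjusted p = 0.497. Pan-endothelial markers were higher in 4 of 16, with the junction cadherin Cdh5 (chromosome 8, 104101625 to 104144511) at 1707 ± 302 against 341 ± 28.2 (log2 fold change 2.31), and lower in 4, with Ramp2 (-2.54), Kdr (-2.06) and Egfl7 (-2.02) (4 and 4 when adjusted over the list alone; camera adjusted p = 0.91). Junction and permeability genes were higher in 3 of 14, with Ocln (2.49) beside Cdh5, and lower in 3, with Cav1 (-2.94) (3 and 3 when adjusted over the list alone; camera adjusted p = 0.699). Vascular growth factor and Notch genes were higher in 7 of 20, with Angpt2 (2.98) and Esm1 (2.65), and lower in 6, with Notch4 (-2.64) (7 and 6 when adjusted over the list alone; camera adjusted p = 0.497). Coagulation and fibrinolysis genes were higher in 10 of 17, with tissue factor F3 at 3.22 and Plat (2.39) and Plaur (2.38), and lower in 2, with the nitric oxide synthase Nos3 at -2.12 (10 and 2 when adjusted over the list alone). For coagulation genes camera gave adjusted p = 0.0182, and adjusted p = 0.423 with an estimated correlation. Arterial markers were higher in 4 of 9, with Hey1 (1.63), and lower in 1, Bmx (-1.56) (4 and 1 when adjusted over the list alone; camera adjusted p = 0.128). Lymphatic markers were higher in 2 of 4, Lyve1 (1.93) and Prox1 (1.47) (2 and 0 when adjusted over the list alone; camera adjusted p = 0.184). Glomerular endothelial markers were higher in 2 and lower in 1 of 5 (2 and 1 when adjusted over the list alone; camera adjusted p = 0.486). DNA methylation and demethylation genes were higher in 6 of 16, with Gadd45g (3.43), Gadd45a (2.41) and Gadd45b (2.08), and lower in 4, with Uhrf1 (-1.68) (6 and 4 when adjusted over the list alone; camera adjusted p = 0.358). DNA methylation itself was not analysed here. The medians of the junction, growth factor, DNA methylation and glomerular lists went from 0.07, 0.16, 0.10 and 0.22 to -0.47, -0.40, -0.42 and -0.34 on RPM as deposited, and that of pan-endothelial markers from -0.29 to -0.85. Between genotypes the higher and lower calls on RPM as deposited were 6 and 6 for transcription factors, 3 and 9 for pan-endothelial markers, 3 and 6 for junction genes, 5 and 8 for growth factor genes, 6 and 4 for coagulation genes, 2 and 1 for arterial markers and 4 and 5 for DNA methylation genes, and counts of the other lists named here differed by at most 1 member.

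Cell cycle genes were lower in SOCS3iKEO in 10 of 16 and higher in 1 (1 and 10 when adjusted over the list alone), with Ccna2 (-3.17) and Birc5 (-2.96). For cell cycle genes camera gave adjusted p = 0.0135, and adjusted p = 0.516 with an estimated correlation. Cholesterol synthesis genes were lower in 10 of 16 (1 and 11 when adjusted over the list alone), with Mvk (-2.34) and Lss (-2.33). For cholesterol genes camera gave adjusted p = 0.012, and adjusted p = 0.427 with an estimated correlation. Oxidative stress and metallothionein genes were higher in 8 of 12 (8 and 0 when adjusted over the list alone), with Mt1 (4.29) and Sod2 (2.16). For oxidative stress genes camera gave adjusted p = 0.00393, and adjusted p = 0.423 with an estimated correlation. Glycocalyx and matrix genes were higher in 10 of 17 and lower in 2 (11 and 2 when adjusted over the list alone), with Adamts4 (3.51) and Sdc1 (3.38). For glycocalyx genes camera gave adjusted p = 0.0117, and adjusted p = 0.423 with an estimated correlation. Glycolysis genes were higher in 6 of 12 and lower in 3, with Hk2 (3.78) and Pfkp (2.64) (6 and 3 when adjusted over the list alone; camera adjusted p = 0.184). Unfolded protein response genes were higher in 7 of 15, with Herpud1 (1.92), and lower in 5, with Sdf2l1 (-2.75) (7 and 5 when adjusted over the list alone). Their list had a median of -0.07, a mean of 0.08 and camera Up at adjusted p = 0.629. The unfolded protein median was 0.01 with RLE scaling and -0.63 on RPM as deposited. Cell death genes were higher in 7 of 18, with Bcl2l11 (3.06) and Tnfrsf10b (2.45), and lower in 2, with Bax (-1.78) (7 and 3 when adjusted over the list alone; camera adjusted p = 0.191). Oxidative phosphorylation genes were higher in 5 of 21, with Uqcrfs1 (1.12) (1 and 0 when adjusted over the list alone; camera adjusted p = 0.0968). Of 8 ribosomal protein genes 1 was higher, Rpl32 (1.14) (0 and 0 when adjusted over the list alone; camera adjusted p = 0.184). The Rpl32 call was lost without SOCS3iKEO LPS 1 (1.11, adjusted p = 0.0878), SOCS3iKEO LPS 2 (1.21, 0.0527), WT LPS 2 (0.97, 0.063) or WT LPS 3 (0.97, 0.0615). It was also lost on RPM as deposited (0.58, 0.15), with no filter on low counts (1.10, 0.0718) and with a sex term (0.59, 0.0874). The medians of the cell death, oxidative phosphorylation and ribosomal lists went from 0.24, 0.26 and 0.43 to -0.31, -0.30 and -0.06 on RPM as deposited. Calls higher and lower on that scale were 0 and 12 for cell cycle genes, 0 and 13 for cholesterol genes, 5 and 0 for oxidative stress genes, 9 and 4 for glycocalyx genes, 3 and 7 for unfolded protein genes, 5 and 6 for cell death genes and 1 and 5 for oxidative phosphorylation genes, and counts of the other lists named here differed by at most 1 member.

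Markers of kidney tubules were higher in SOCS3iKEO after LPS. Proximal tubule markers were higher in 12 of 14 (14 and 0 when adjusted over the list alone), with Slc22a8 (3.36) and Slc5a2 (3.26). For proximal tubule markers camera gave adjusted p = 3.92e-06, and adjusted p = 0.423 with an estimated correlation. Their summed deposited RPM was 3995 and 3022 in SOCS3iKEO LPS, 1255, 1449 and 2054 in WT LPS and 2593 to 2758 in saline libraries. Loop of Henle markers were higher in 4 of 6 (4 and 0 when adjusted over the list alone), with Egf (4.04) and the cotransporter Slc12a1 at 14.3 ± 7.04 against 0.723 ± 0.387 scaled RPM (log2 fold change 3.09). For loop of Henle markers camera gave adjusted p = 0.0182, and adjusted p = 0.423 with an estimated correlation. All 4 distal convoluted tubule markers were higher, with Slc12a3 (3.28) (4 and 0 when adjusted over the list alone). For distal tubule markers camera gave adjusted p = 0.0136, and adjusted p = 0.423 with an estimated correlation. Principal cell markers were higher in 5 of 6, with Scnn1b (2.44) (6 and 0 when adjusted over the list alone). For principal cell markers camera gave adjusted p = 0.0117, and adjusted p = 0.423 with an estimated correlation. Intercalated cell markers were higher in 5 of 6, with Slc26a4 (1.91) (6 and 0 when adjusted over the list alone). For intercalated cell markers camera gave adjusted p = 0.0242, and adjusted p = 0.516 with an estimated correlation. Injured tubule markers were higher in 5 of 7, with Krt20 (3.56) and Sox9 (2.81) (6 and 0 when adjusted over the list alone). For injured tubule markers camera gave adjusted p = 0.0242, and adjusted p = 0.423 with an estimated correlation. The Krt20 call was lost without SOCS3iKEO LPS 1 (3.31, adjusted p = 0.122), SOCS3iKEO LPS 2 (3.91, 0.0619), WT LPS 2 (2.73, 0.0662) or WT LPS 3 (2.98, 0.0742). It was also lost with edgeR (2.31, 0.161), DESeq2 (2.40, 0.603), no filter on low counts (3.53, 0.0997) and a sex term (1.94, 0.131). The injured tubule markers summed to 1086 and 1119 deposited RPM in SOCS3iKEO LPS and to 1084, 192 and 322 in WT LPS, so WT LPS 1 stood apart from the other WT LPS libraries and at the SOCS3iKEO level. Neutrophil markers were higher in 5 of 6, with S100a9 (1.96) and S100a8 (1.66) (6 and 0 when adjusted over the list alone). For neutrophil markers camera gave adjusted p = 0.0163, and adjusted p = 0.423 with an estimated correlation. Neutrophil markers summed to 37.0 and 17.4 deposited RPM. The S100a8 call was lost without SOCS3iKEO LPS 1 (1.45, adjusted p = 0.0534). Podocyte markers were higher in 2 of 6 (2 and 0 when adjusted over the list alone; camera adjusted p = 0.497). Mural and mesangial markers were higher in 1 of 7, Acta2 (1.76) (1 and 0 when adjusted over the list alone; camera adjusted p = 0.262). Macrophage markers were higher in 1 of 7, Csf1r (1.62) (1 and 0 when adjusted over the list alone; camera adjusted p = 0.384). Fibroblast markers were lower in 1 of 5 (0 and 0 when adjusted over the list alone; camera adjusted p = 0.629). Platelet markers were higher in 1 of 3, Itga2b (1.19) (2 and 0 when adjusted over the list alone; camera adjusted p = 0.184). Both tested urothelial markers were higher, with Upk1a (2.50), and the erythroid marker did not pass. The T and NK cell marker Lck was lower (-1.39), a call lost without SOCS3iKEO LPS 1 (-1.03, adjusted p = 0.0529). Housekeeping genes were lower in 1 of 6 (0 and 1 when adjusted over the list alone). Housekeeping genes had a median of 0.11, a mean of -0.18 and camera Down at adjusted p = 0.777. The podocyte and housekeeping medians on RPM as deposited went from 0.18 and 0.11 to -0.34 and -0.42. Sex-linked genes passed in 0 of 4 (0 and 0 when adjusted over the list alone; camera adjusted p = 0.267, median -3.15). For these markers RPM as deposited gave higher and lower calls of 10 and 0 for proximal tubule markers, 2 and 0 for intercalated cell markers, 1 and 2 for podocyte markers and 0 and 3 for housekeeping genes, and counts of the other lists named here differed by at most 1 member.

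Between genotypes after LPS limma called 6503 genes, 3076 higher and 3427 lower in SOCS3iKEO, with 2191 and 2403 past a 2-fold change. Camera called 21 of 43 lists, 19 up and 2 down, and 0 with an estimated correlation. On RPM as deposited the split was 1721 higher and 5346 lower (24.4% higher instead of 47.3%), with the median of all genes at -0.45 instead of -0.04. All SOCS3iKEO libraries and 1 of the 3 WT LPS libraries lacked reads on Y-linked genes, so genotype and sex were partly confounded. The call of Kdr was lost while its fold stayed close to -2.06, at -1.74 with a sex term (adjusted p = 0.051) and -2.10 with no filter on low counts (0.0504).

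**Figure D3:**
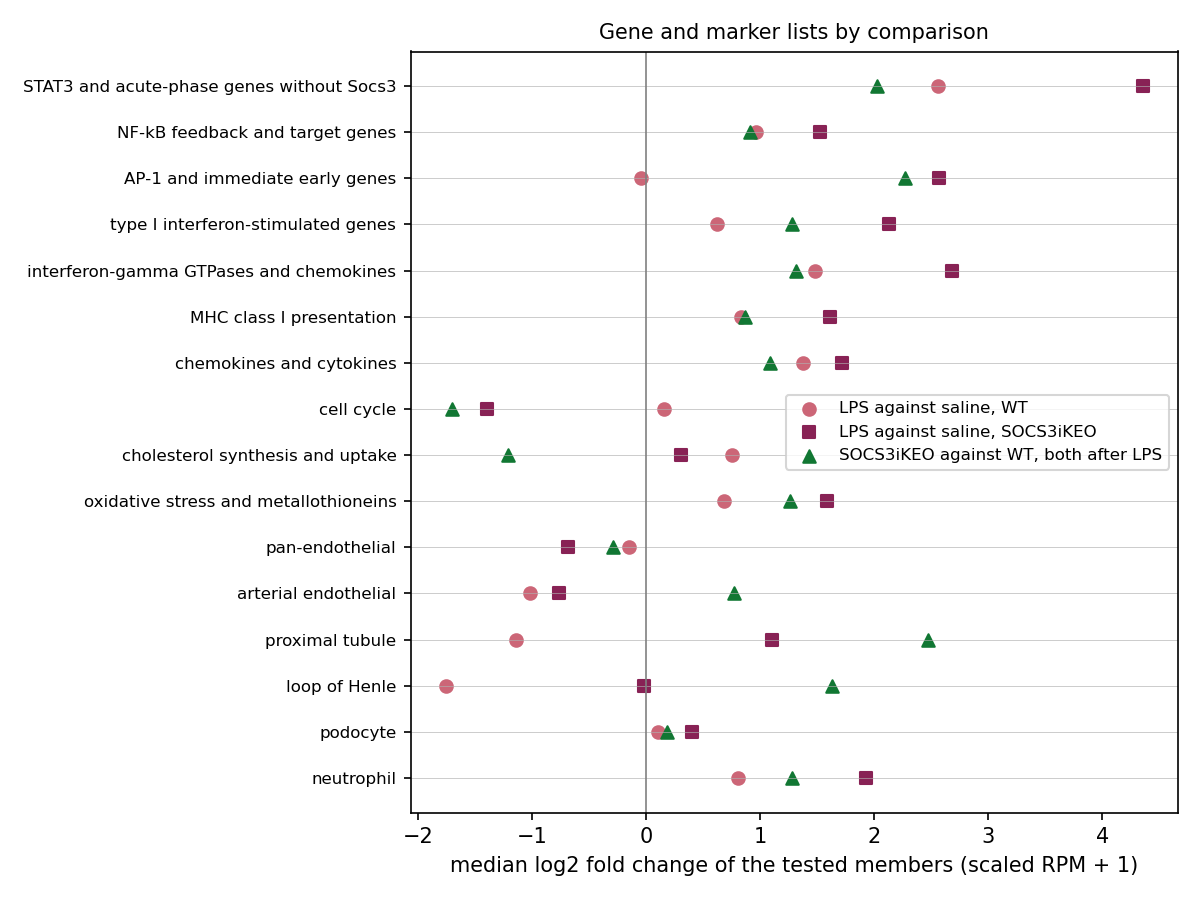
Median log2 fold change of 16 fixed gene lists in 3 comparisons, LPS against saline in WT, LPS against saline in SOCS3iKEO and SOCS3iKEO against WT after LPS. The proximal tubule list lies at -1.14, 1.11 and 2.47, and the STAT3 and acute-phase list at 2.56, 4.35 and 2.02.

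Whether the LPS response itself differed between genotypes was tested as an interaction. Cebpd rose more in SOCS3iKEO than in WT, by 5.94 on the log2 scale (SE 0.69, adjusted p = 0.00344), as did Cxcl11 at 5.84, Akap12 at 5.33 and Il6 at 5.30 and the ubiquitin ligase Rnf125 at 5.28. Pkn3, a protein kinase, had a more negative response in SOCS3iKEO by -5.40 (SE 0.73, adjusted p = 0.00531), as had Lyl1 at -4.75, Arhgap27 at -4.70, Exoc3l2 at -4.65 and Slc9a3r2 at -4.56. AP-1 and immediate early genes had a more positive response in 10 of 16 (14 and 0 when adjusted over the list alone). For AP-1 genes camera gave adjusted p = 6.91e-07, and adjusted p = 0.529 with an estimated correlation. Type I interferon-stimulated genes had one in 11 of 22 (15 and 0 when adjusted over the list alone). For interferon-stimulated genes camera gave adjusted p = 1.2e-05, and adjusted p = 0.529 with an estimated correlation. STAT3 and acute-phase genes had one in 8 of 18 (11 and 0 when adjusted over the list alone). For STAT3 and acute-phase genes camera gave adjusted p = 0.00137, and adjusted p = 0.566 with an estimated correlation. Oxidative stress genes had a more positive response in 6 of 12 (6 and 0 when adjusted over the list alone). For oxidative stress genes camera gave adjusted p = 0.00164, and adjusted p = 0.529 with an estimated correlation. Proximal tubule markers had one in 11 of 14 (11 and 0 when adjusted over the list alone). For proximal tubule markers camera gave adjusted p = 3.7e-06, and adjusted p = 0.529 with an estimated correlation. Cell cycle genes had a more negative response in 5 of 16 and a more positive one in 1 (1 and 6 when adjusted over the list alone). For cell cycle genes camera gave adjusted p = 0.0128, and adjusted p = 0.594 with an estimated correlation. More positive and more negative responses on RPM as deposited numbered 8 and 0 for interferon-stimulated genes, 6 and 0 for STAT3 and acute-phase genes, 3 and 0 for oxidative stress genes, 7 and 0 for proximal tubule markers and 1 and 8 for cell cycle genes, and counts of the other lists named here differed by at most 1 member. Limma called 2366 genes, 1149 positive and 1217 negative. On RPM as deposited it called 621 and 2561 (19.5% positive instead of 48.6%, with the median of all genes at -0.44 instead of -0.01). The count was 238 without WT saline 1, 754 without WT saline 2, 971 without WT LPS 2, 1040 without WT LPS 3, 3678 without SOCS3iKEO LPS 2 and 843 with no filter on low counts. Akap12 lost its call without WT saline 1 (5.41, adjusted p = 0.0894), WT saline 2 (5.24, 0.0755), SOCS3iKEO LPS 1 (4.75, 0.0709) or WT LPS 3 (5.11, 0.06) and with edgeR (4.99, 0.0785). Il6 lost it without WT saline 1 (5.35, 0.0588) and with DESeq2 (1.92, 0.576) or edgeR (2.27, 0.765). Exoc3l2 lost it without WT saline 1 (-4.48, 0.0514) and Slc9a3r2 without WT saline 1 (-4.54, 0.0723) or WT saline 2 (-4.56, 0.0545). With no filter on low counts all 4 lost their calls at log2 differences of 5.28, 5.26, -4.69 and -4.60, at adjusted p of 0.0532 to 0.0962. This contrast equals that between the 2 runs of animal numbers and rests on 1 SOCS3iKEO saline library.

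After saline, SOCS3iKEO (1 library) was compared with WT (n = 2). Ube2o, a ubiquitin-conjugating enzyme (chromosome 11, 116537740 to 116581447), had the smallest p, at 0.226 against 12.6 ± 5.67 scaled RPM (log2 fold change -3.41, SE 0.40, adjusted p = 0.148), and did not pass. Lcn2 was at 5.54 against 1.4 ± 0.379, Serpina3g at 14.1 against 2.42 ± 0.757 and Tmem207 at 1.47 against 11.7 ± 6.29, each with an adjusted p of 1. Of the fixed lists, STAT3 and acute-phase genes passed camera upward (median 0.46), with 0 of 18 members past the test (2 and 0 when adjusted over the list alone). For STAT3 and acute-phase genes camera gave adjusted p = 0.000725, and adjusted p = 0.84 with an estimated correlation. Fibroblast markers also passed upward (median 0.87) with 0 of 5 members past the test (0 and 0 when adjusted over the list alone). For fibroblast markers camera gave adjusted p = 0.00748, and adjusted p = 0.84 with an estimated correlation. Cholesterol synthesis genes passed downward (median -0.43) with 0 of 16 members past the test (0 and 0 when adjusted over the list alone). For cholesterol genes camera gave adjusted p = 0.0272, and adjusted p = 0.84 with an estimated correlation. Limma called 0 genes, with 423 at an unadjusted p under 0.05. DESeq2 called 5, among them Ube2o, Lcn2 and Serpina3g, edgeR 0, 1 (Ube2o) was called both by limma on log2 CPM and with a pseudocount of 0.1 (adjusted p = 0.044 and 0.046), and 2 were called with no filter on low counts.

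Over both genotypes together, LPS (n = 5) was compared with saline (n = 3) with genotype as a covariate. The genes that rose most were Lcn2 at 10.42, Mctp2 at 7.31, Serpina3f at 6.76 and Ifi205 at 6.72 on the log2 scale, with Csf3, listed at 0 in all 3 saline libraries, and those that fell most were Igfbp5 at -4.81, Npr3 at -4.74, Btnl9 at -4.71, Chrm3 at -4.02 and Nrep at -3.91. For each, all LPS libraries lay on one side of all saline ones, as the naming rule required. Limma called 2907 genes, 1304 higher and 1603 lower after LPS, with 891 and 1162 past a 2-fold change. On RPM as deposited it called 697 and 3624 (16.1% higher instead of 44.9%, with the median of all genes at -0.46 instead of -0.07). The count was 1762 without WT saline 2 or SOCS3iKEO LPS 2 and 1621 without WT LPS 1. It was 1401 without the genotype covariate. Adding the run, which equals the interaction, gave 5986.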

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

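The tests on GC content and length, on the share of endothelial RNA and on TMM scaling were chosen only after the results were seen, as were the fits with a term for Y-linked reads over all libraries and on RPM as deposited. The LPS response differed between genotypes, by the interaction test, in 2366 genes. The same contrast separates the 2 runs of animal numbers (WT saline and SOCS3iKEO LPS against WT LPS and SOCS3iKEO saline), so a different LPS response cannot be told apart from a shift between runs on top of a genotype effect that is the same after saline and LPS. A shift between runs alone is taken up below. The genes with the largest differences of the LPS log2 fold change (SOCS3iKEO minus WT) were Cebpd at 5.94, Cxcl11 at 5.84, Akap12 at 5.33, Il6 at 5.30 and Rnf125 at 5.28, and Pkn3 at -5.40, Lyl1 at -4.75, Arhgap27 at -4.70, Exoc3l2 at -4.65 and Slc9a3r2 at -4.56.

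A first pattern was the size of the genotype difference after LPS (n = 2 against 3), with 6503 genes called. A bias by the GC content or length of the transcript is argued against, since 6462 genes were called after that correction, 6075 of them among the original calls in the same direction. The GC content and length of the amplicons were not known, so a bias by these was not tested. A shift between the 2 runs as the whole cause is argued against: it would enter the saline comparison with the opposite sign, but the slope of the saline on the LPS genotype difference over called genes was 0.0428 (0.00 and 0.08 against each WT saline library), where -1 would be needed. Sex and genotype cannot be told apart: within the 5 LPS libraries 3344 genes were called with a term for Y-linked reads and 6272 of 6272 kept their sign, with a median ratio of 0.88, but only 1 WT LPS library lacked Y-linked reads. A partial shift between runs and the genotype named in the labels stay open as well.

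Tubule markers were higher in SOCS3iKEO after LPS, including abundant members, chosen here for their level after it was seen: Kap at 1885 ± 107 against 956 ± 196 scaled RPM and Miox at 836 ± 254 against 93.1 ± 19.0. The median of 36 tubule markers exceeded that of 25 podocyte, mural, fibroblast and macrophage markers by 1.63 on the log2 scale (2.0 against 0.37). The two-sided permutation p was 1e-05, the smallest that 100000 permutations can give. With blood cells and urothelium added (38 markers) the excess was 1.36 (two-sided permutation p = 1e-05). The permutations shuffled genes between lists, so p treats markers as independent and does not measure the spread between mice. Mural and macrophage markers were also low (sums of 8.91 to 35.4 and 4.59 to 23.3 deposited RPM), where the log2(value + 1) scale shrinks changes. Among markers at 1 scaled RPM or more (34 and 20) the difference was 1.63. Within these limits a lower share of endothelial RNA as the whole cause is argued against. TMM scaling as the cause is argued against by a median of 1.50 and a lower quartile of 0.82 on RPM as deposited. Against saline of the same genotype the tubule median was 0.81 in SOCS3iKEO (0.14 on RPM as deposited) and -1.03 in WT (-1.31 on RPM as deposited). The fall in WT was thus larger than the rise in SOCS3iKEO, and made up most of the difference on RPM as deposited. The 13 blood cell and urothelium markers alone were higher by a median of 1.08 (neutrophil 1.28, urothelium 1.70, platelet 0.90), so a lower endothelial share may contribute, as may more tubule RNA in the purified fraction or a change within tubule cells, which were not tested.

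For LPS over both genotypes, the 8 libraries make 56 splits into 5 and 3, and the 1 that equals the genotype covariate could not be fitted. Of the other 55, 1, the real one, gave as many as 2907 genes, and the highest of the other splits gave 1402. This argues against chance, but only at the level of 1 in 55 splits, the rarest result possible here. The splits also did not keep the number of LPS libraries within each genotype. The split with 1402 genes set SOCS3iKEO LPS 1 and 2 and WT LPS 1 against the rest. These are the LPS libraries without Y-linked reads. WT saline 1 and SOCS3iKEO saline, on the other side, also lack them (2 and 3 reads). The split is thus not by sex alone, and its cause was not tested.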

How the results depend on the processing

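The alternatives chosen after seeing the data are listed as such in the first section, from edgeR to lists on log2 CPM. No paired analysis was possible because the groups share no replicate numbers in the labels. Of 238 values of genes open to naming, 228 passed the threshold, 0 of these reversed and 169 of the 238 kept sign and side in every alternative fixed beforehand. Of the calls, 61 lost the threshold in at least 1 of those and 218 in at least 1 of all settings, mostly in the 5 libraries without Y-linked reads. Leaving out 1 library gave 348 to 2553 genes changed by LPS in WT, 238 to 3678 for the interaction and 1621 to 2662 for LPS over both genotypes, with fewer samples as part of the cause. No filter on low counts gave 1078 for LPS in WT and 843 for the interaction, with more genes to adjust for. The 5 libraries without Y-linked reads gave 0 for LPS in WT, LPS in SOCS3iKEO, genotype after LPS and interaction, a fit with 1 residual degree of freedom that says nothing on stability. The same libraries gave 1401 for LPS over both genotypes (2 residual degrees of freedom). On all 8, no covariate also gave 1401, and adding the run, which equals the interaction, 5986. Between genotypes after saline, where limma called 0, no filter gave 2, DESeq2 5, log2 CPM 1 and pseudocount 0.1 1, and the cause was not tested. With an estimated correlation 0 lists passed in either list comparison. The estimated form also tests on 4 residual degrees of freedom, and the cause was not tested. Without SOCS3iKEO saline, LPS over both genotypes was WT only and others needing it were not run. Socs3, with fold changes near 0 and not called between genotypes, changed sign after LPS (-0.11) with the GC correction (0.0944), thinned reads (0.0884) and leaving out 1 library (-0.60 to 0.57). It did after saline (-0.11) leaving out 1 library (-0.28 to 0.0761), and in the interaction (-0.01) with RLE (0.0532), DESeq2 (0.0379), log2 CPM (0.21), pseudocount 0.1 (0.24), the GC correction (0.16), thinned reads (0.20) and leaving out 1 library (-0.49 to 0.67). The cause was not tested. Depth set a floor of 0.202 to 0.423 RPM, near which Socs3 lay after saline.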

Other observations

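In the libraries labelled SOCS3iKEO, further lists moved with LPS. Glycocalyx and matrix remodelling genes rose in 10 of 17 and 2 fell (10 and 2 when adjusted over the list alone). For glycocalyx genes camera gave adjusted p = 0.00218, and adjusted p = 0.329 with an estimated correlation. Oxidative stress and metallothionein genes rose in 8 of 12 (8 and 0 when adjusted over the list alone). For oxidative stress genes camera gave adjusted p = 8.57e-05, and adjusted p = 0.337 with an estimated correlation. Ribosomal protein genes rose in 7 of 8 (8 and 0 when adjusted over the list alone). For ribosomal protein genes camera gave adjusted p = 0.00218, and adjusted p = 0.431 with an estimated correlation. Glycolysis genes rose in 7 of 12 and 1 fell (7 and 2 when adjusted over the list alone). For glycolysis genes camera gave adjusted p = 0.0249, and adjusted p = 0.337 with an estimated correlation. JAK-STAT components rose in 12 of 22 and 4 fell (13 and 5 when adjusted over the list alone). For JAK-STAT genes camera gave adjusted p = 0.0143, and adjusted p = 0.329 with an estimated correlation. Cell cycle genes fell in 9 of 16 and 2 rose (2 and 10 when adjusted over the list alone; camera adjusted p = 0.0774), with Ccna2 at 29 scaled RPM after saline and 2.5 ± 2.54 after LPS. The numbers of these lists that rose and fell on RPM as deposited were 10 and 4 for glycocalyx genes, 3 and 0 for ribosomal protein genes, 6 and 4 for glycolysis genes, 7 and 6 for JAK-STAT genes and 0 and 11 for cell cycle genes, and counts of the other lists named here differed by at most 1 member. The saline arm is 1 library.

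The test of the STAT3 list was chosen only after the result was seen. A hypothesis was that the larger LPS response of SOCS3iKEO would be particular to STAT3 and acute-phase genes, which Socs3 restrains. By the interaction the result was negative: the median interaction was 1.24 for that list (18 members), against 2.36 for AP-1 and immediate early genes (16 members), 1.41 for type I interferon-stimulated genes, 1.19 for the interferon-gamma list and 0.46 for NF-kB genes. The difference of -1.12 from the AP-1 list had a two-sided permutation p of 0.0168, which does not account for AP-1 being the highest of the other lists. Between genotypes after LPS the medians of the STAT3 and AP-1 lists were 2.02 and 2.27 (two-sided permutation p = 0.639), and after saline 0.46 and -0.27 (two-sided permutation p = 0.0054). The difference in the interaction thus came largely from the saline comparison, of 1 SOCS3iKEO and 2 WT libraries, and after LPS the lists were not told apart. Which of the saline libraries it came from was not tested. As above, the permutations do not measure the spread between mice.

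Ube2o was close to absent in every library labelled SOCS3iKEO, a pattern singled out after its values were seen. In RPM as deposited it had 10.9 and 20.8 in WT saline and 16.8, 19.2 and 18.5 in WT LPS (155 to 309 reads), but 0.119 and 0.071 in SOCS3iKEO LPS and 0.282 in SOCS3iKEO saline (1, 1 and 2 reads). Between genotypes after LPS its log2 fold change was -4.04. With limits also chosen after seeing Ube2o, it was the only 1 of 12820 tested genes at 5 scaled RPM or more in all 5 WT and under 1 in all 3 SOCS3iKEO libraries, and 0 genes met the reverse. Ube2o starts 1428339 bases from the start of Socs3 on chromosome 11. A candidate explanation is a sequence difference of the SOCS3iKEO animals linked to the Socs3 locus, which could also stop the amplicon from being read. Of 169 tested genes within 10 Mb of Socs3, Ube2o and Socs3 left out, 10 (5.92%) differed after saline at an unadjusted p under 0.05. Elsewhere 403 of 12460 did (3.23%, two-sided Fisher's exact test, p = 0.0747). Of the 10, those nearest Ube2o (1810032O08Rik, BC018473, Mxra7 and 2900041M22Rik) kept their sign after LPS (2.64, 2.81, -3.75 and -2.71). Cbr2, D11Wsu47e and Zfp750 did not. The hypothesis stays undecided.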
